A study of Mus musculus with 60 samples.

How the data were processed

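The samples were undifferentiated mouse embryonal carcinoma cells of 6 strains: P19, its subclone P19CL6, and 4 sublines of P19CL6 named CL6G26, CL6G36, CL6G45 and CL6G52. Embryonal carcinoma cells are the pluripotent stem cells of teratocarcinomas, and P19 is a line that can be made to form neural or mesodermal derivatives; P19CL6 is known as a subclone that readily forms beating cardiac muscle. The labels give the source as a male C3H mouse embryo and name 5 biological replicates per strain, each measured on 2 Affymetrix array types, MOE430A and MOE430B, which makes 60 arrays. Per the labels' protocols, the cells were grown in alpha-MEM with fetal calf serum, total RNA was isolated with an RNeasy Mini kit, and biotin-labelled cRNA was made with a two-cycle kit. The labels do not say whether the replicates came from separate cultures or passages, so p-values measure the spread between these samples, part of which may be technical.

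The deposited values are GCOS signals, per the submitters' processing notes, which give no version; the unit is a linear intensity per probe set, and the values the authors deposited were taken as they stand. The target of any global scaling is not given in the sources used here. The CEL files were not used here. No 2 deposited columns were identical. The 2% trimmed mean signal ran from 96.6 to 183.3 on MOE430A, up to 34.9% off the mean over the 30 arrays, and from 18.62 to 30.42 on MOE430B, up to 25.08% off. Because these exceeded the limit of 5% set for equal scaling, the arrays of each type were quantile normalized, and the deposited scaling was kept as an alternative. Signals under 1 were set to 1 and log2 was taken.

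Each array type held 64 control probe sets, which were left out. Of the 22690 probe sets on MOE430A, the platform annotation gives 1 gene symbol for 20380, several for 691 and no gene for 1555. Of the 22575 on MOE430B it gives 1 symbol for 14661, several for 245 and no gene for 7605. Genes were named from probe sets with 1 symbol, and a check against current gene records changed 0 symbols. A probe set was tested if it lay above the floor on at least 5 of the 30 arrays of its type. The floor was the 40th percentile of the array on MOE430A and the 60th on MOE430B, which after normalization is a log2 signal of 4.61 and 4.14. This left 15068 and 12131 probe sets and 13181 genes, of which 8906 were read on MOE430A and 4275 on MOE430B. A gene was read from the probe set with the highest mean signal, with probe sets of the x_at kind used where a gene had no other; of the 2111 genes with tested probe sets on both array types, the MOE430A value was taken.

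Tests used limma version 3.58.1 in R version 4.3.3, with a group-means model over all 30 arrays of a type, eBayes with a trend in mean signal, and Benjamini-Hochberg adjustment over the probe sets tested within an array type for each comparison. The spread was thus estimated with 24 residual degrees of freedom over 6 strains. P19CL6 was compared with P19 and each subline with P19CL6; the 4 sublines were compared among themselves with a moderated F test. A gene was called with an adjusted p under 0.05 and a change of at least 2-fold; for the F test the 2-fold limit applied to the range of the subline means. Tests were two-sided. Fold changes are given as differences of mean log2 signal with the standard error (SE) of the fit, and levels as mean ± SD over 5 arrays. A gene under the floor on every array of a group has a bound there: the change is given as at least N-fold, the mean of the brighter group against the floor, with the adjusted p of the fit. Where the mean of a group lies under the floor but some of its arrays above it, the change with signals raised to the floor is given.

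The test, the samples, the filter, 31 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The named genes are, for each comparison, those called with no overlap between the arrays of the 2 groups: the 6 largest increases and 6 largest decreases among genes above the floor on all arrays of both groups (8 and 8 for P19CL6 against P19), and in each direction the 4 with the smallest adjusted p among genes above the floor on all arrays of one group and under it on all arrays of the other. Fewer are given where fewer met the rule. Clone and model names were left out, and 1 gene that the rule names is not reported here. Further named are the 10 genes with the largest range among the sublines, genes called the same way in all 4 sublines, up to 4 members of each list described, and Pou5f1, Nanog, Sox2, Klf4, Zfp42, T, Gata4, Gata6, Nkx2-5 and Mef2c. Genes named outside this rule are said to be so, and Pdia6, Tnfrsf19, Epha2, Eomes, Id3, Fgf5, Bst2, Hspa5, Bbc3, Lefty1, Ddit3, Asz1, Kdm5d and Eif2s3y were, in at least 1 comparison, named outside it after their values were seen.

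The lists were shared pluripotency, naive pluripotency, primed epiblast, primitive streak and mesoderm, cardiac transcription factor, cardiac contractile, neural, endoderm, trophoblast, blood and endothelial, fibroblast, germ cell, Wnt ligand and target, BMP and TGF-beta, Notch, FGF and ERK feedback, retinoid, imprinted, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle, p53 target, unfolded protein response, heat shock, interferon and MHC, extracellular matrix and adhesion, Y chromosome, X inactivation, ribosomal protein, and DNA and histone methylation enzyme genes. They were tested on MOE430A genes with limma's camera at its preset correlation of 0.01, where at least 4 members were tested, with Benjamini-Hochberg adjustment over the lists of a comparison. That left 28 lists and 140 tests over the 5 comparisons. Of the 584 genes listed, 28 stand in more than 1 list. A member rose or fell if its limma adjusted p over all probe sets was under 0.05; the count adjusted over the list alone is given beside it, and both counts cover the members tested on either array type. For list members and the genes given in each strain, where the rule for called genes does not name them, a call means an adjusted p under 0.05 without the 2-fold limit. Where a list call is lost with a correlation estimated from the data, that adjusted p is given with the range over the alternatives.

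Alternatives tried were the deposited scaling, median centring, an offset added before log2 or signals raised to the floor, no filter or a stricter filter, the mean of a gene's probe sets, eBayes without the trend, a fit on the 2 strains alone (4 sublines alone for the F test), the replicate number as a block, each array left out in turn, camera with an estimated correlation, and fry, which tests a list against no change and not against the other genes. Added after the data were seen were fits without P19 replicates 4 and 5, and without these and CL6G52 replicate 1. The contrasts between pairs of sublines were also added then. Calls were counted in 100 splits or relabellings of the arrays. The overlap between comparisons that share the P19CL6 arrays was set beside 20 simulations of unchanged groups, beside independent lists of the same length, and beside a split of the P19CL6 arrays into replicates 1 and 2 and replicates 3 to 5, or among 3 comparisons; a lone control array is then assumed to vary like the other groups.

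The pipeline was tested on simulated signals for CL6G36 against P19CL6 with 13318 genes passing the filter. Of genes changed by 0.5, 1 and 2 log2 units, 27.7%, 66.7% and 85.7% had an adjusted p under 0.05, and 0%, 33.3% and 85.7% were called. Among 13124 unchanged genes, 5 had an adjusted p under 0.05. All 26 lists shifted by 0.5 one at a time were recovered. The simulated genes varied independently of each other. In the data the estimated correlation ran from -0.032 for interferon and MHC genes to 0.351 for cholesterol synthesis genes. The recovery thus does not test lists whose members vary together. The number of arrays, 5 per strain and type, limits the precision. Figures were drawn with matplotlib version 3.10.9 under Python version 3.11.15, with pandas version 2.3.3 and numpy version 2.4.6.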

Results

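Transcript levels were measured in undifferentiated cells of 6 mouse embryonal carcinoma strains on a pair of oligonucleotide arrays, MOE430A and MOE430B. The strains were the parental line P19, its subclone P19CL6, and the P19CL6 sublines CL6G26, CL6G36, CL6G45 and CL6G52, with 5 replicates each and 60 arrays in all. The labels do not state what the sublines were derived for. The comparisons made were P19CL6 against P19, each subline against P19CL6, and the 4 sublines among themselves. After filtering, 13181 genes were tested. Median array signals ran from 30.2 to 53.4 on MOE430A and from 10.6 to 16.5 on MOE430B, and the number of arrays limits the precision.

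On MOE430A the arrays of CL6G36 and CL6G45 lay side by side, the P19CL6 and CL6G26 arrays lay together, and P19 replicates 1, 2 and 3 stood far from every other array. P19 replicates 4 and 5 did not lie with the other P19 replicates but among the P19CL6 arrays, and CL6G52 replicate 1 lay with CL6G45. The P19CL6 arrays were spread too, as noted after their values were seen. On component 1, P19CL6 replicates 1 and 2 stood at -3.81 and -1.69 and replicates 3 to 5 at -13.8 to -11.6. Those 2 replicates read 5.85 and 7.09 against 4.27 to 4.87 for Ddit3, 5.66 and 5.28 against 6.81 to 7.07 for Sp5, and 7.03 and 6.97 against 8.11 to 8.25 for Lgals3. The first and second principal components held 19.3% and 9.64% of the variance on MOE430A, and 6.78% and 5.51% on MOE430B. The ratio of the Gapdh 3' to 5' probe sets, a sign of RNA integrity and of the labelling, ran on MOE430A from 0.908 to 0.954 in P19 and from 0.835 to 0.887 in P19CL6, while on MOE430B these ranges overlapped, at 0.815 to 0.916 and 0.829 to 0.878. On MOE430A it ran from 0.829 to 0.883 in CL6G26, from 0.820 to 0.927 in CL6G36, from 0.795 to 0.875 in CL6G45 and from 0.781 to 0.856 in CL6G52.

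**Figure D1:**
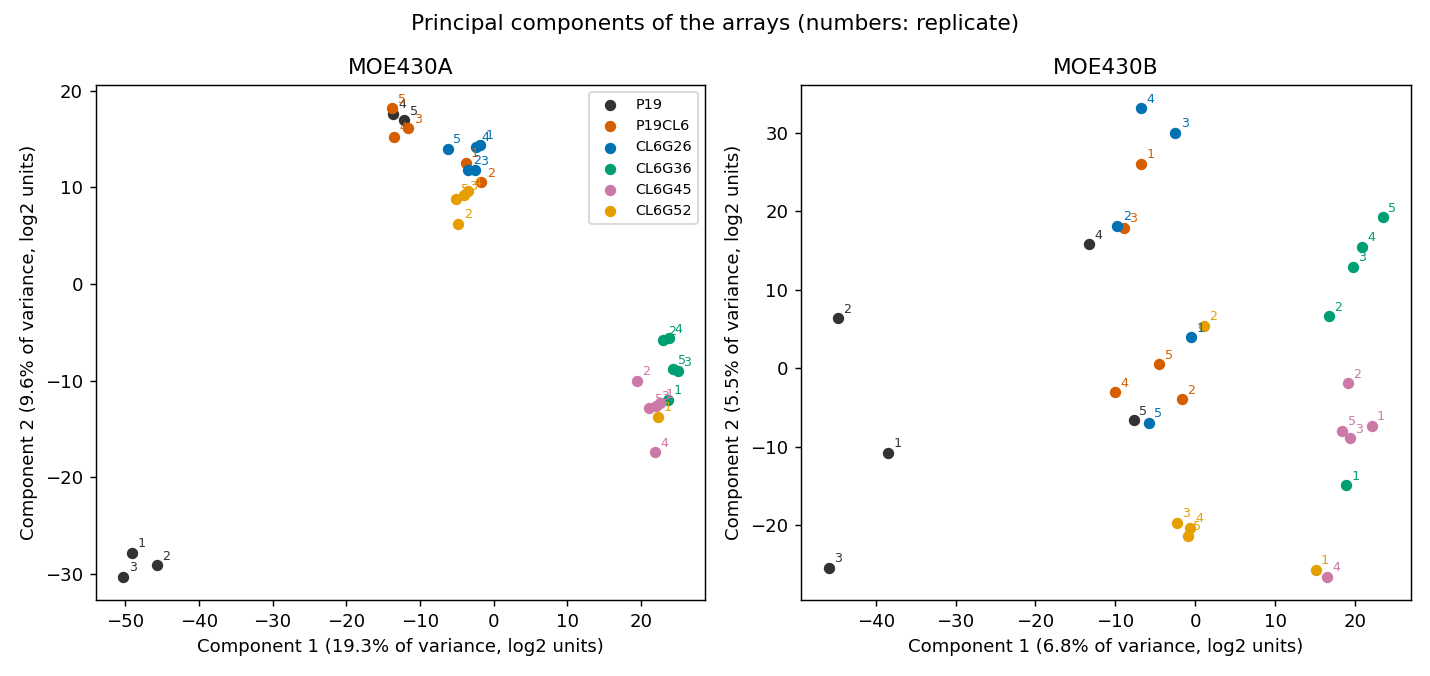
First and second principal components of the normalized log2 signals on MOE430A and MOE430B, with 1 point per array and 1 colour per strain; axis labels give the percent of variance. P19 replicates 4 and 5 lie with P19CL6, and CL6G52 replicate 1 lies with CL6G45, on MOE430A.

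Pou5f1, the transcription factor Oct4 that maintains pluripotency, was bright in every strain, with mean log2 signals from 11.24 ± 0.14 in CL6G52 to 11.59 ± 0.08 in CL6G36 (SD, n = 5), and passed the test in none of the 5 comparisons. Without CL6G52 replicate 1, the difference of Pou5f1 between CL6G52 and P19CL6 passed, at -0.25 on the log2 scale (limma, adjusted p = 0.00353, range over its alternatives 0.000465 to 0.747), and over 22 alternatives it passed 4 times in CL6G52, 4 times in CL6G36 and 2 times for P19CL6 against P19. Nanog, a second factor of the pluripotency network, had levels of 8.73 ± 0.12 in P19, 8.76 ± 0.12 in P19CL6 and 8.76 ± 0.08 in CL6G26. Nanog fell in CL6G36 to 7.66 ± 0.34, a change of -1.10 ± 0.12 (SE, limma, adjusted p = 3.50e-08), and in CL6G45 to 7.74 ± 0.15, a change of -1.02 ± 0.12 (adjusted p = 2.97e-07). Nanog fell in CL6G52 by 0.66 on the log2 scale (adjusted p = 0.000575), and missed the threshold with the deposited scaling (adjusted p = 0.262, range over its alternatives 0.000268 to 0.262). Sox2, their partner, lay between 8.60 and 8.97 and passed in no comparison. It passed under 5 of 22 alternatives in CL6G36 (adjusted p from 0.0332 to 0.567) and under 3 of 22 for P19CL6 against P19 (0.00528 to 0.761).

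Gata4, Gata6 and Nkx2-5, transcription factors of endoderm and heart precursors, lay near the floor of 4.61, with means of 4.07 to 5.01, 4.83 to 5.52 and 5.10 to 5.35. Gata6 fell in CL6G36 by 0.69 (adjusted p = 0.00926) and in CL6G45 by 0.60 on the log2 scale (adjusted p = 0.0239). Gata6 missed the threshold in both with the deposited scaling (adjusted p = 0.105 and 0.339, the highest over their alternatives, from 0.00316 and 0.0119), and in CL6G45 it did so under 5 of 22 alternatives in all. Gata4 in CL6G45 differed by -0.94 with an adjusted p of 0.0512, and 8 of 22 alternatives put it past the threshold (range 0.0219 to 0.275), with a change of -0.29 when signals are raised to the floor. Nkx2-5 passed nowhere. The brightest probe sets of Klf4 and Zfp42, markers of naive pluripotency, lay above the floor on 0 of 30 arrays and that of Mef2c, a muscle regulator, on 1 of 30. None of their probe sets met the filter, so they were not tested. T, the mesoderm regulator brachyury, had no probe set with a single gene name and is not analysed here.

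P19CL6 and P19, the subclone and its parental line, differed in 86 genes, of which 65 were higher and 21 lower in P19CL6. Of the 86 genes, 29 lay above the floor on all arrays of both groups. Npy, which encodes neuropeptide Y, rose by 1.49 ± 0.30 on the log2 scale, to 11.01 ± 0.07 from 9.52 ± 1.25 (adjusted p = 0.0121), and Pltp, a phospholipid transfer protein, rose to 8.17 ± 0.08 from 7.17 ± 0.82 (adjusted p = 0.0121). No P19 array lay near that mean of Npy. It read 8.64, 8.51 and 8.69 in P19 replicates 1 to 3. In P19 replicates 4 and 5 it read 10.9 and 10.87, close to the P19CL6 range of 10.91 to 11.08. The SE rests on the spread within all 6 strains, which is narrower for Npy in P19CL6 than in P19. Shroom2, a regulator of cell shape through actomyosin, fell by 1.01 on the log2 scale with an SE of 0.19 (adjusted p = 0.0295), and Rslcan18, a zinc finger gene, was at least 1.76-fold higher in P19CL6 (adjusted p = 0.0301). By adjusted p alone 588 genes passed, but 48 with the deposited scaling. That count was 0 without P19 replicate 1, 2 or 3, 1460 and 1502 without P19 replicates 4 and 5, and 260 to 389 without any 1 of the P19CL6 replicates. Of all genes tested, 2.23% did not overlap between the 5 and 5 arrays, against 0.794% by chance, and 14 of the called genes were among them.

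Genes chosen after their values were seen show the spread within P19. Cited1, a transcriptional coactivator, read 2.07, 4.18 and 1.66 in P19 replicates 1 to 3 but 10.31 and 10.44 in replicates 4 and 5, against 10.44 ± 0.03 in P19CL6. Trh, the thyrotropin-releasing hormone precursor, read 11.13, 11.29 and 11.29 in P19 replicates 1 to 3 and 5.16 and 4.41 in replicates 4 and 5, while P19CL6 ran from 4.44 to 5.17. Meg3, a maternally expressed imprinted RNA, read 7.86, 8.09 and 7.96 and then 4.62 and 3.47. Dppa4, a gene of pluripotent cells, read 7.45, 7.40 and 7.47 and then 4.88 and 4.88. Bhlhe40, a clock-linked repressor, read 1.33, 3.04 and 1.09 and then 6.97 and 7.18. Without P19 replicate 1, 2 or 3 the count fell to 0 in limma, with 1945, 1992 and 1918 genes at an unadjusted p under 0.05, and without replicate 4 or 5 it was 198 or 192. A fit on the 2 strains alone called 0 genes, with 2133 at an unadjusted p under 0.05, the deposited scaling called 47, and the fit without P19 replicates 4 and 5, added after the data were seen, called 390.

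The named genes of this comparison rest on the same arrays. Npy had an adjusted p of 0.0669, 0.0615 and 0.0687 without P19 replicates 1, 2 and 3, and its adjusted p ran from 2.24e-18 to 0.194 over its alternatives. Pltp ran from 2.74e-12 to 0.194, Shroom2 from 1.08e-15 to 0.409 and Rslcan18 from 0.000418 to 0.409. The calls of Npy, Pltp, Shroom2 and Rslcan18 were lost under 4, 8, 13 and 13 of 22 alternatives.

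Cell cycle genes fell in P19CL6 (camera, adjusted p = 0.00653, median -0.08), with 6 of 29 members down, none up and 7 down adjusted over the list alone. With an estimated correlation the adjusted p = 0.431, the highest over the alternatives, from 0.00145. Among them the G1 cyclins Ccnd1 and Ccnd2 fell by 0.82 and 0.75 on the log2 scale, Ccne1, which drives entry into S phase, fell by 0.60 and Mad2l1, of the spindle checkpoint, fell by 0.41. Glycolysis genes rose (adjusted p = 0.0424, median 0.16), with 3 of 17 up and 6 adjusted over the list alone; adjusted p = 0.692 with an estimated correlation, and from 0.00186 to 0.692 over the alternatives. Pfkfb3, an activator of phosphofructokinase, rose by 1.10, the pyruvate dehydrogenase kinase Pdk1 by 0.64 and the phosphofructokinase Pfkm by 0.47. Cholesterol synthesis genes rose as a list (adjusted p = 0.0424, median 0.14), though limma put 0 of 17 members past the threshold, 5 at an unadjusted p under 0.05, all higher, and 0 adjusted over the list alone; adjusted p = 0.692 with an estimated correlation, and from 0.00309 to 0.692 over the alternatives. The members named here lost their calls without P19 replicate 1, 2 or 3. Over 22 alternatives Pdk1 lost its call 13 times, Pfkfb3 10, Ccne1 8, Pfkm 6, and Ccnd1, Ccnd2 and Mad2l1 5 times each. The Gapdh ratios of P19 lay above those of P19CL6 with no overlap on MOE430A but overlapped them on MOE430B. The cholesterol call ended without P19 replicates 1, 2 or 3 or P19CL6 replicates 3 or 5, and that of glycolysis without P19 replicates 1 or 3 or P19CL6 replicate 2 (adjusted p from 0.0655 to 0.0955). The strict filter ended both (0.0579), and fry, which tests a list against no change and not against other genes, gave 0.193 for both.

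**Figure D2:**
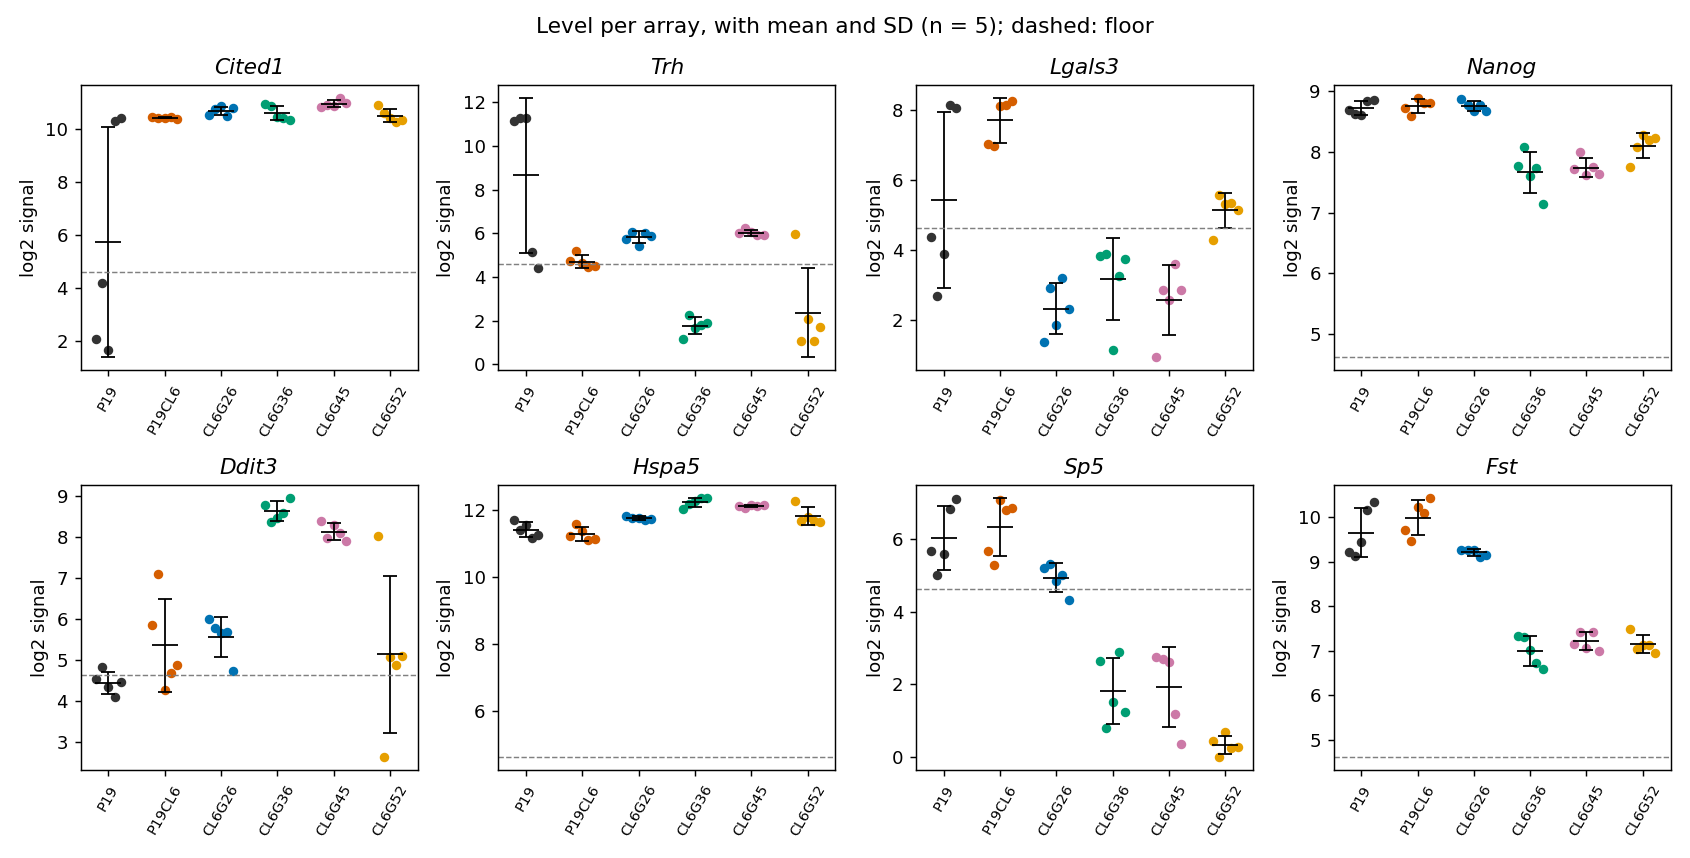
Normalized log2 signals of Cited1, Trh, Lgals3, Nanog, Ddit3, Hspa5, Sp5 and Fst on MOE430A, with 1 point per array, bars for the mean and SD of 5 arrays, and a dashed line at the floor of 4.61. P19 replicates 4 and 5 sit with P19CL6 for Cited1 and Trh, and Ddit3 is above 7.8 on the arrays of CL6G36 and CL6G45.

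CL6G26 differed from P19CL6 in 34 genes, of which 7 were higher and 27 lower. Of the 34 genes, 15 lay above the floor on all arrays of both groups. Ret, a receptor tyrosine kinase for glial-derived neurotrophic factors, rose by 1.68 ± 0.17, to 7.04 ± 0.10 from 5.35 ± 0.44 (adjusted p = 1.03e-07), and Mest, an imprinted gene expressed from the paternal allele, rose by 1.05 ± 0.10 (adjusted p = 2.00e-08). Snx7, a sorting nexin, rose by 1.36 ± 0.24 (adjusted p = 0.00338), a call lost with the deposited scaling (adjusted p = 0.0997, range 9.20e-06 to 0.0997). Plin2, a coat protein of lipid droplets, was at least 3.42-fold lower (adjusted p = 3.63e-09) and Lpl, lipoprotein lipase, fell by 1.49 on the log2 scale (SE 0.13, adjusted p = 1.06e-08).

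Lgals3, which encodes galectin-3, was at least 8.48-fold lower in CL6G26 (adjusted p = 1.80e-05), and Ctsc, a lysosomal cysteine protease, at least 2.90-fold lower (adjusted p = 9.86e-07). Cep41, a centrosomal protein, fell by 1.73, Ptgr1, a prostaglandin reductase, by 1.73, Cited2, a transcriptional coregulator, by 1.71 and Laptm4b, a lysosomal membrane protein, by 1.60 (log2 changes of -1.73 ± 0.14, -1.73 ± 0.17, -1.71 ± 0.18 and -1.60 ± 0.22; the highest adjusted p was 1.64e-05, for Laptm4b). Ifitm1, an interferon-induced membrane protein, was at 6.55 ± 0.22 against 8.05 ± 0.80, a change of -1.50 ± 0.28 (adjusted p = 0.00186). Acyp2, an acylphosphatase, was at least 1.16-fold lower (adjusted p = 0.000391) and lost its call with signals raised to the floor or the 2 strains alone. By adjusted p alone 164 genes passed, 4.15% of genes did not overlap between the groups (30 of them called). The deposited scaling called 22, with 34 by adjusted p alone.

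Of the lists, 5 passed in CL6G26 and 3 held with an estimated correlation. Cardiac contractile genes fell (adjusted p = 5.04e-06, median -0.40), with 3 of 10 down and 5 adjusted over the list alone: Tagln, an actin-binding protein of smooth muscle, fell by 2.08 on the log2 scale, Actc1, cardiac actin, fell by 0.97 and Tpm1, a tropomyosin, fell by 0.41. Wnt ligands and targets fell (adjusted p = 0.00739, median -0.32), with Sfrp1, a secreted Wnt antagonist, down by a log2 change of -1.29 as the 1 member of 18 past the threshold and 1 adjusted over the list alone. Interferon and MHC genes fell (adjusted p = 0.00593, median -0.23), with 2 of 13 down, Ifitm1 and the interferon regulatory factor Irf1 at -0.71, and 4 adjusted over the list alone. Unfolded protein response genes, which restore protein folding in the endoplasmic reticulum, rose (adjusted p = 1.81e-07, median 0.24), with 5 of 18 up and 7 adjusted over the list alone; adjusted p = 0.131 with an estimated correlation, the highest over the alternatives, from 1.02e-10. The transcription factor Xbp1 rose by 0.89, Sdf2l1, a chaperone cofactor, by 0.53, Hspa5, the main lumenal chaperone, by 0.47 and the disulfide isomerase Pdia6 by 0.43. The p53 targets fell as a list (adjusted p = 0.000141, median -0.36) with 0 of 15 members past the limma threshold, 6 at an unadjusted p under 0.05, all lower, and 3 down adjusted over the list alone; adjusted p = 0.173 with an estimated correlation, the highest over the alternatives, from 5.66e-07. With the deposited scaling Actc1, Tpm1, Hspa5, Irf1 and Sfrp1 missed the threshold, and Tpm1 did so under 7 of 22 alternatives. The CL6G26 means of Tagln, Actc1 and Sfrp1 lay under the floor, and with signals raised to it they changed by -1.89, -0.84 and -1.12. Pdia6 missed the threshold with the mean of its probe sets.

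CL6G36 differed from P19CL6 in 192 genes, 69 higher and 123 lower. Of the 192 genes, 86 lay above the floor on all arrays of both groups. Derl3, which helps export misfolded proteins for degradation, rose by 2.53 ± 0.26, to 8.25 ± 0.40 from 5.72 ± 0.16 (adjusted p = 2.75e-08), and Creld2, a secreted protein induced by stress of that compartment, rose by 1.65 ± 0.14 (adjusted p = 2.45e-10). Fst, the activin antagonist follistatin, fell by 2.99, to 6.99 ± 0.34 from 9.99 ± 0.40 (adjusted p = 1.45e-12), and Fgf8, a growth factor of the primitive streak, fell by 1.98 (adjusted p = 1.42e-09), both on the log2 scale. Mixl1, a homeobox gene of mesendoderm, was at least 4.65-fold lower (adjusted p = 1.92e-10).

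Further increases in CL6G36 were those of H2-DMa, an MHC class II chaperone, at 2.05 ± 0.16, Hip1r, an endocytic adaptor, at 1.76 ± 0.29, Jcad, a junctional protein, at 1.72 ± 0.19, and Aldh1l2, a mitochondrial folate enzyme, at 1.67 ± 0.24 (the highest adjusted p was 5.77e-05, for Hip1r). Gpr37, an orphan receptor, was at least 4.04-fold, Trim66, a chromatin-linked protein, at least 2.75-fold, Chst1, a sulfotransferase, at least 1.49-fold and Mfsd6, a transporter-like protein, at least 1.47-fold higher. Tmem98, a membrane protein, changed by -2.37 ± 0.21, Pdf, a mitochondrial deformylase, by -2.14 ± 0.14, Egr1, an immediate early factor downstream of ERK, by -1.67 ± 0.25, and Amot, a Hippo pathway scaffold, by -1.64 ± 0.12 (the highest adjusted p was 1.49e-05, for Egr1). Sall3, a zinc finger factor, was at least 6.77-fold lower, Nkx1-2, of the caudal epiblast, at least 2.49-fold lower and Nenf, a secreted neurotrophic factor, at least 1.63-fold lower. By adjusted p alone 1786 genes passed, and 12.3% of genes did not overlap, 166 of them called. The deposited scaling called 153, with 329 by adjusted p alone. Mfsd6 and Nenf lost their calls with signals raised to the floor, Amot fell short of 2-fold with the mean of all its probe sets (-0.83) and Chst1 did so under 3 of 22 alternatives, among them without P19CL6 replicate 5 (0.80).

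The unfolded protein response was the list with the smallest adjusted p in CL6G36: 16 of 18 members rose, none fell, 17 rose adjusted over the list alone (camera, adjusted p = 5.79e-19, median 0.77; adjusted p = 0.00384 with an estimated correlation). Ddit3, the stress-induced factor CHOP, rose by 3.27 ± 0.53, Herpud1, of the degradation complex, by 1.62, Trib3, a pseudokinase induced by the same stress, by 1.59, and Xbp1 by 1.38. The Gapdh ratio lay outside the range of P19CL6 on 6 of the 10 MOE430A arrays of CL6G36 and CL6G45, and 0 of these 10 samples lay inside it on both array types. Glycolysis genes rose (adjusted p = 0.000108, median 0.24), with 9 of 17 up, among them Aldoc by 0.87 and Pfkp by 0.60, and 11 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation, the highest over the alternatives, from 1.13e-05. Heat shock genes fell (adjusted p = 0.0128, median -0.19), with 3 of 10 down, 1 up and the same numbers adjusted over the list alone; adjusted p = 0.0878 with an estimated correlation, the highest over the alternatives, from 2.90e-05. The cytosolic chaperones Hsph1 and Dnaja1 changed by -0.96 and -0.62, and Hspa4l by 0.51.

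Some lists of the early embryo and its signals fell in CL6G36, while those of pluripotency, trophoblast, Notch and retinoid genes did not pass. Wnt ligands and targets had 8 of 18 members down and 9 adjusted over the list alone (adjusted p = 2.35e-05, median -0.55): Sp5, a direct Wnt target, was at least 3.30-fold lower, Wnt5b at least 1.39-fold lower, and Axin2, a feedback inhibitor of the pathway, and Tnfrsf19, a receptor, changed by -1.42 and -1.18. Primed epiblast genes had 8 of 17 down and 8 down and 1 up adjusted over the list alone (adjusted p = 9.88e-05, median -0.26), with Wnt8a at -1.69, Epha2, an ephrin receptor, at -1.15 and Nodal, the TGF-beta ligand of the epiblast, at -0.91. Primitive streak and mesoderm genes had 5 of 16 down and 6 adjusted over the list alone (adjusted p = 0.00143, median -0.35), with the T-box factor Eomes at -1.34 ± 0.15. BMP and TGF-beta genes had 6 of 16 down and 8 adjusted over the list alone (adjusted p = 1.68e-05, median -0.32). Among them were Msx1, a homeobox target of BMP, at -1.64 and the inhibitors of differentiation Id1 and Id3 at -1.03 and -0.72. FGF and ERK feedback genes had 8 of 16 down and 9 down and 1 up adjusted over the list alone (adjusted p = 9.88e-05, median -0.42), with Etv4, an ETS factor, at -1.37 and Fgf5 at -0.82. With signals raised to the floor the medians of the Wnt, epiblast, streak and FGF lists were -0.37, -0.20, -0.14 and -0.37. Wnt8a and Msx1, whose CL6G36 means lay under the floor, then changed by -1.20 and -1.17.

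Endoderm genes fell too (adjusted p = 0.00378, median -0.40), with 3 of 12 down and 5 adjusted over the list alone, among them Foxa2, a factor of endoderm and axial mesoderm, at -1.99 ± 0.18 and the laminin Lamb1 at -0.71. Interferon and MHC genes fell (adjusted p = 0.00114, median -0.32), with 5 of 13 down, 1 up, and 6 down and 1 up adjusted over the list alone. Ifitm1 fell by 3.58, Oas1a, an antiviral enzyme, by 1.56 and Irf1 by 0.94, while Bst2, an antiviral tether, rose by 0.45 (log2 changes of -3.58, -1.56, -0.94 and 0.45). With signals raised to the floor, under which their CL6G36 means lay, Ifitm1 and Oas1a changed by -3.30 and -1.06. Cardiac contractile genes fell (adjusted p = 0.0315, median -0.50), with 3 of 10 down, among them Tagln at -1.19, and 4 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation, and from 0.000529 to 0.469 over the alternatives. That call also ended with no filter (0.469), the strict filter (0.0690) and the mean of all probe sets (0.0917). Without the filter the contractile median was -0.22, and with the deposited scaling Aldoc, Pfkp, Hspa4l and Bst2 missed the threshold. Bst2 also missed it without P19CL6 replicate 4, and Pfkp missed it under 5 of 22 alternatives.

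CL6G45 showed 182 called genes, 61 higher and 121 lower, and with the deposited scaling 155, of which 83 were higher and 72 lower, so the share of higher calls moved from 33.5% to 53.5%. That scaling shifted the median of all genes by 0.12 in CL6G45, 0.13 in CL6G26 and 0.11 in CL6G52. Derl3 rose by 1.78 ± 0.26 (adjusted p = 1.55e-05), Xbp1 by 1.64 ± 0.16, to 10.53 ± 0.05 from 8.89 ± 0.42 (adjusted p = 2.81e-08), and Herpud1 by 1.53 ± 0.35 (adjusted p = 0.00221). Fst fell by 2.77, to 7.21 ± 0.20 from 9.99 ± 0.40 (adjusted p = 5.71e-11), Fgf8 fell by 1.78 (adjusted p = 2.81e-08) and Mixl1 fell by 1.77 on the log2 scale (adjusted p = 7.65e-07).

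Aldh1l2 rose in CL6G45 by 1.87 ± 0.24 and Cebpb, a stress-responsive factor, by 1.49 ± 0.23 (the highest adjusted p was 2.57e-05, for Cebpb). Trim66 was at least 2.53-fold, Mfsd6 at least 1.68-fold, Rin1, a Ras effector, at least 1.38-fold and Gpr85, an orphan receptor, at least 1.31-fold higher. Ifitm1 changed by -2.84 ± 0.28, Cited2 by -1.84 ± 0.18 and Apela, a peptide hormone of early embryonic cells, by -1.63 ± 0.21 (the highest adjusted p was 8.87e-06, for Apela). Lgals3 was at least 8.48-fold lower, Sall3 at least 6.77-fold, Sp5 at least 3.30-fold and Irx3, a homeobox gene, at least 2.43-fold lower. By adjusted p alone 1747 genes passed, and 13.7% of genes did not overlap, 160 of them called. With the deposited scaling 385 passed by adjusted p alone. Of the 182 called genes, 77 lay above the floor on all arrays of both groups. The count of called genes fell to 112 with signals raised to the floor, under which Mfsd6, Rin1 and Gpr85 lost their calls.

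Unfolded protein response genes rose in CL6G45, with 16 of 18 members up, none down and 16 adjusted over the list alone (camera, adjusted p = 1.44e-17, median 0.77; adjusted p = 0.00994 with an estimated correlation). Ddit3 rose by 2.77 ± 0.53, Trib3 by 1.43, and Hspa5 by 0.83 ± 0.10. Glycolysis genes rose (adjusted p = 0.00168, median 0.18), with 6 of 17 up and 6 adjusted over the list alone, among them Aldoc by 1.14 and Pfkp by 0.79; adjusted p = 0.286 with an estimated correlation, the highest over the alternatives, from 1.83e-05. Median centring ended that call (0.0699). Cholesterol synthesis genes rose (adjusted p = 0.0462, median 0.20), with 3 of 17 up and 1 down and 5 up and 1 down adjusted over the list alone; adjusted p = 0.483 with an estimated correlation, and from 0.00821 to 0.483 over the alternatives, 12 of 44 of which, with fry counted among them, missed the threshold. Fdps and Cyp51, enzymes of sterol synthesis, rose by 0.55 and 0.49 and Idi1 fell by 0.24 on the log2 scale, all 3 lost with the deposited scaling and the last under 7 of 22 alternatives. The p53 targets fell (adjusted p = 0.0197, median -0.47), with 8 of 15 down and 1 up and 8 down and 2 up adjusted over the list alone; adjusted p = 0.344 with an estimated correlation, the highest over the alternatives, from 0.00123. The kinase Plk2 changed by -1.50, Cdkn1a, the p21 inhibitor of the cell cycle, by -1.31, and Bbc3, the cell death activator PUMA, by 0.77. Heat shock genes fell (adjusted p = 0.00573, median -0.13), with 4 of 10 down, among them Hsph1 at -0.90, and 4 adjusted over the list alone; adjusted p = 0.0519 with an estimated correlation, the highest over the alternatives, from 1.68e-05.

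In CL6G45, Wnt ligands and targets fell (adjusted p = 6.16e-06, median -0.79), with 7 of 18 down and 8 adjusted over the list alone, among them Tnfrsf19 at -1.47 and Axin2 at -1.30. Primitive streak and mesoderm genes fell (adjusted p = 0.00224, median -0.41), with 5 of 16 down and 5 adjusted over the list alone; Evx1, a homeobox gene of the posterior streak, was at least 3.29-fold lower and Eomes was at 8.02 ± 0.18 against 9.02 ± 0.21. Endoderm genes fell (adjusted p = 0.00179, median -0.29), with 5 of 12 down and 5 adjusted over the list alone, among them Foxa2 at -1.38 and the basement membrane collagen Col4a2 at -1.51. Interferon and MHC genes fell (adjusted p = 0.00187, median -0.28), with 5 of 13 down and 7 adjusted over the list alone, among them Irf1 at -0.87. Cardiac contractile genes fell (adjusted p = 0.00608, median -0.48), with 3 of 10 down and 3 adjusted over the list alone, among them Tagln at -1.76; no filter ended the call (0.364, range 2.20e-05 to 0.364), with a median of -0.08. With signals raised to the floor the medians of the Wnt, streak and contractile lists were -0.47, -0.25 and -0.33.

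Primed epiblast genes fell in CL6G45 (adjusted p = 0.0246, median -0.08), with 8 of 17 down, among them Fgf8 and Nkx1-2 (-1.28 with signals raised to the floor, under which its CL6G45 mean lay), 2 up, and 8 down and 3 up adjusted over the list alone. The median crossed 0 over its alternatives (-0.22 to 0.07), and the call ended with the strict filter (0.0748) and the 2 strains alone (0.164, range 3.45e-07 to 0.164). It also ended without P19 replicates 4 and 5 (0.0677) and without these and CL6G52 replicate 1 (0.0915). BMP and TGF-beta genes fell (adjusted p = 0.0113, median -0.24), with 5 of 16 down and 1 up and 6 down and 1 up adjusted over the list alone; adjusted p = 0.0569 with an estimated correlation, the highest over the alternatives, from 8.29e-06. Id1 changed by -1.35 ± 0.21 and Nodal by -0.75, while Lefty1, a Nodal antagonist, changed by 0.59, a call lost under 14 of 22 alternatives. FGF and ERK feedback genes fell (adjusted p = 0.0286, median -0.25, or -0.13 with signals raised to the floor), with 4 of 16 down and 4 adjusted over the list alone; adjusted p = 0.0569 with an estimated correlation, and from 2.51e-05 to 0.0637 over the alternatives. Egr1 changed by -1.05 and Spry4, a feedback inhibitor, by -0.94 (-0.52 with signals raised to the floor, under which its CL6G45 mean lay), both lost with the deposited scaling. That list's call ended without P19CL6 replicate 1 (0.0581) or CL6G45 replicate 4 (0.0637) with the mean of all probe sets (0.0574), and without P19 replicates 4 and 5 and CL6G52 replicate 1 (0.0567). The cholesterol call ended without P19CL6 replicates 1, 2 or 4 or CL6G45 replicates 1 or 3 (0.0563 to 0.0759).

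CL6G52 differed from P19CL6 in 66 genes, 14 higher and 52 lower, and with the deposited scaling in 56, of which 32 were higher and 24 lower, which moved the share of higher calls from 21.2% to 57.1%. Fst fell by 2.84, to 7.15 ± 0.20 from 9.99 ± 0.40 (adjusted p = 1.55e-11), Fgf8 fell by 2.08 (adjusted p = 2.87e-09), Foxa2 fell by 1.89 (adjusted p = 2.61e-08) all on the log2 scale, and Axin2 fell to 6.29 ± 0.11 from 7.78 ± 0.19 (adjusted p = 2.26e-07). Sp5 was at least 3.30-fold lower (adjusted p = 2.87e-09). Among the increases, Dnmt3a, the de novo DNA methyltransferase, rose by 1.02 ± 0.18, to 9.32 ± 0.06 from 8.30 ± 0.34 (adjusted p = 0.000439), and Pgm2, a phosphoglucomutase, rose by 1.20 ± 0.13 (adjusted p = 4.12e-07).

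Frmd4a, a scaffold of cell polarity, rose in CL6G52 by 1.34 ± 0.24 (adjusted p = 0.00182) and Trap1a, an X-linked tumour antigen gene, by 1.08 ± 0.29 (adjusted p = 0.0279). Ifitm1 changed by -2.35 ± 0.28 and Mixl1 by -1.56 ± 0.21; Sall3 was at least 6.77-fold, Nkx1-2 at least 2.49-fold and Meis2, a homeobox cofactor, at least 1.99-fold lower. Of the 66 called genes, 24 lay above the floor on all arrays of both groups. By adjusted p alone 419 genes passed, and 4.89% of genes did not overlap, 53 of them called. The count by adjusted p alone was 171 with the deposited scaling, 252 with the 2 strains alone, 266 without P19CL6 replicate 4 and 644 without CL6G52 replicate 1. Trap1a lost its call with the deposited scaling (0.0548) and without P19CL6 replicates 3, 4 or 5 or CL6G52 replicates 2 or 3 (0.0586 to 0.0695; range over its alternatives 5.71e-07 to 0.0695). Dnmt3a fell short of 2-fold without P19CL6 replicates 3, 4 or 5 or CL6G52 replicate 1, and with the mean of its probe sets (0.67); Meis2 did so with signals raised to the floor (-0.99).

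Wnt ligands and targets fell in CL6G52 (camera, adjusted p = 4.02e-08, median -0.61, or -0.38 with signals raised to the floor), with 6 of 18 down and 8 adjusted over the list alone, among them Tnfrsf19 at -1.05. BMP and TGF-beta genes fell (adjusted p = 7.76e-07, median -0.47, or -0.31 with signals raised to the floor), with 3 of 16 down, Fst, Nodal at -0.62 and Id3 at -0.47, and 8 adjusted over the list alone. Primitive streak and mesoderm genes fell (adjusted p = 0.000556, median -0.19, or -0.14 with signals raised to the floor), with 5 of 16 down, among them Eomes at -1.40, and 6 adjusted over the list alone. FGF and ERK feedback genes fell (adjusted p = 0.00135, median -0.25, or -0.19 with signals raised to the floor), with 4 of 16 down, 1 up, and 6 down and 1 up adjusted over the list alone, among them Egr1 at -1.02. Primed epiblast genes fell by their test (adjusted p = 0.00532), with 5 of 17 down and 7 down and 1 up adjusted over the list alone; their median was -0.02, from -0.08 to 0.05 over the alternatives, and their mean was -0.39. Interferon and MHC genes fell (adjusted p = 9.63e-05, median -0.31), with Ifitm1 as the 1 member of 13 past the threshold and 5 adjusted over the list alone.

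Cholesterol synthesis genes fell in CL6G52 (adjusted p = 9.30e-07, median -0.29), with 4 of 17 down and 9 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation, the highest over the alternatives, from 2.11e-12. Mvk, mevalonate kinase, changed by -0.66 and Fdft1, squalene synthase, by -0.49. Endoderm genes fell (adjusted p = 0.0347, median -0.24), with 2 of 12 down, Foxa2 and the apolipoprotein Apoe at -0.65 (a call lost under 13 of 22 alternatives), and 4 down and 1 up adjusted over the list alone; adjusted p = 0.10 with an estimated correlation, and from 0.000938 to 0.232 over the alternatives. Unfolded protein response genes rose (adjusted p = 0.000383, median 0.23), with 5 of 18 up and 8 up and 1 down adjusted over the list alone; adjusted p = 0.280 with an estimated correlation, the highest over the alternatives, from 2.52e-06. Xbp1 rose by 0.70 and Pdia6 by 0.63, while Ddit3 differed by -0.22 (adjusted p = 0.879). Ddit3 read 8.01 in replicate 1, which lay with CL6G45, and 2.62 to 5.08 in replicates 2 to 5; without replicate 1 the list's median was 0.12 (0.155). The endoderm call ended without CL6G52 replicate 1 (0.175) or P19CL6 replicates 3 or 5 (0.0556 and 0.0623) and with the mean of all probe sets (0.0602). For the unfolded protein response fry, which tests another question, gave 0.0536. Both calls also ended without P19 replicates 4 and 5 and CL6G52 replicate 1 (0.232 and 0.196). With the deposited scaling Nodal, Id3, Egr1, Xbp1, Mvk, Fdft1 and Apoe missed the threshold in CL6G52.

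**Figure D3:**
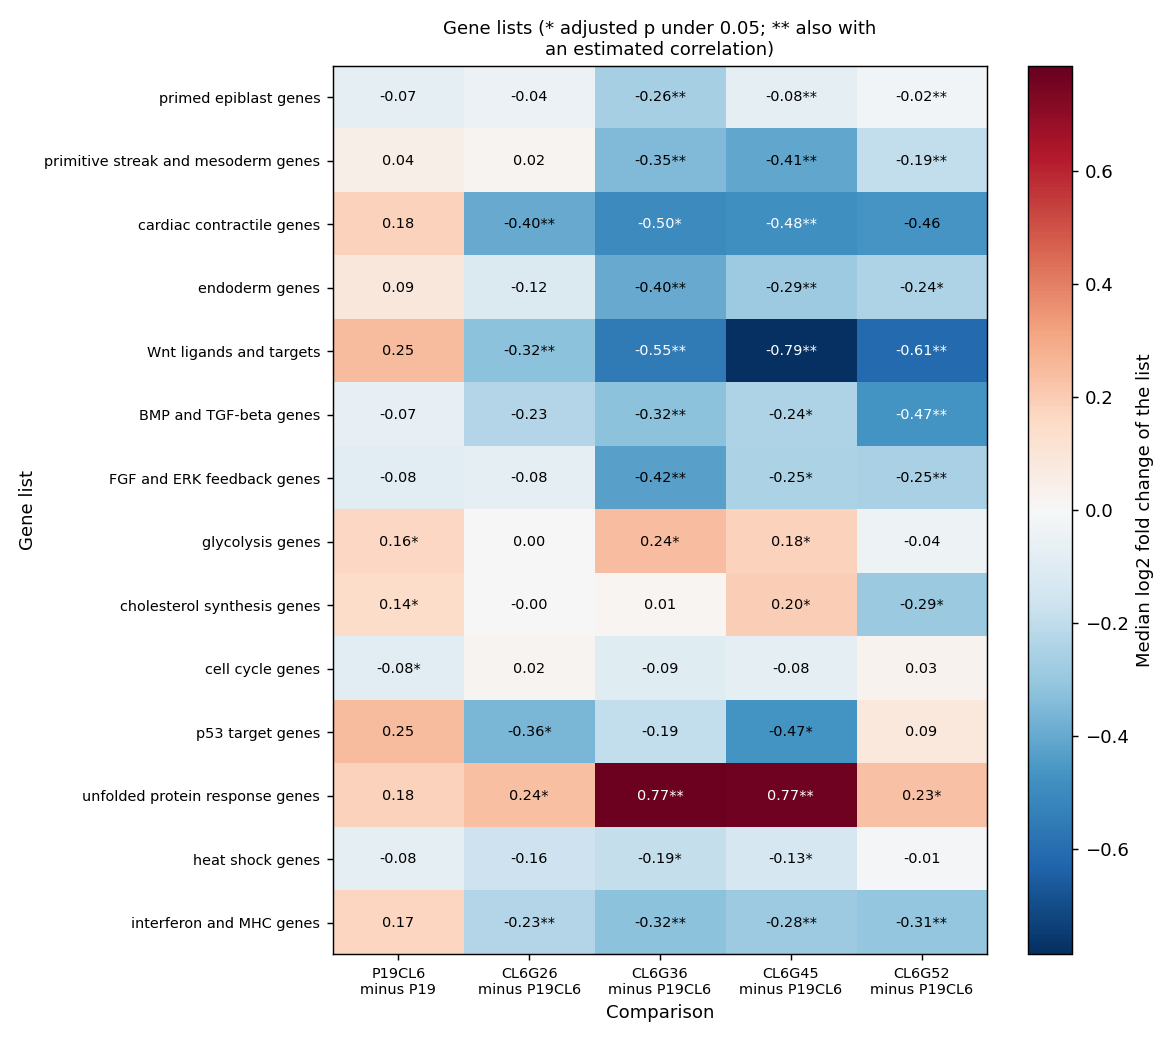
Median log2 fold changes in the 5 comparisons for the 14 lists that passed in at least 1 of them. A mark shows where a list passed the threshold and another where it held with an estimated correlation. Tested lists that passed in no comparison are not drawn. Unfolded protein response genes have medians of 0.77 in CL6G36 and CL6G45, and Wnt ligands and targets lie below 0 in all 4 sublines.

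The sublines differed among themselves in 398 genes (limma moderated F test, with 3052 at an adjusted p under 0.05, or 1219 with the deposited scaling). Derl3 had the largest range among genes above the floor on all 20 arrays, 2.73 on the log2 scale, from 8.25 ± 0.40 in CL6G36 to 5.52 ± 0.85 in CL6G52 (adjusted p = 4.86e-09). Tmem98 was at 6.82 ± 0.28 in CL6G36 and at 9.20, 9.25 and 9.54 in CL6G26, CL6G45 and CL6G52 (range 2.72, adjusted p = 7.07e-11). H2-DMa at 7.17 and Sorcs2, a sorting receptor of neurons, at 7.45 were highest in CL6G36, with the other sublines between 5.21 and 5.27 and between 5.51 and 5.60. Pdf and Tmem59l, a membrane protein of the brain, were lowest there, at 5.17 and 5.48. Snx7 was highest in CL6G26, at 8.43, as was Fst, at 9.21 against 6.99 to 7.21. Crabp2, which carries retinoic acid to the nucleus, ran from 7.74 in CL6G36 to 5.66 in CL6G45.

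Contrasts between pairs of sublines were added after the data were seen. In these, 67 genes were called for CL6G45 against CL6G36, 174 for CL6G45 against CL6G26 and 195 for CL6G36 against CL6G26. For CL6G52, 94 were called against CL6G26, 111 against CL6G45 and 169 against CL6G36. The counts for CL6G52 include its replicate 1, which lies with CL6G45, and were not made without it. Against P19CL6, CL6G36 and CL6G45 shared 90 calls, 30 higher and 60 lower. Lists drawn independently would share 0.319 and 1.13. Unchanged groups simulated against the same P19CL6 arrays shared at most 0, but such groups have few calls to share. That simulated count does not show what the shared arrays add among changed genes. With the P19CL6 arrays split between the comparisons of CL6G36 and CL6G45, 40 or 44 calls were shared. The covariance of their fold changes was 0.109 against a simulated 0.0361, a difference of 0.0729, and r across genes, which are not independent replicates, was 0.640 against a simulated 0.498. CL6G36 and CL6G52 shared 40 calls (23 or 14 with split controls, 38 without CL6G52 replicate 1) and CL6G45 and CL6G52 shared 38 (22 or 15, and 34 without that array, which lies with CL6G45). Their r was 0.480 and 0.530, against simulated values of 0.499 and 0.502, and their covariance 0.0713 and 0.0780, against simulated values of 0.0363 and 0.0364. Without CL6G52 replicate 1, for which no simulation was run, r was 0.392 and 0.411 and the covariance 0.0616 and 0.0641. CL6G26 shared 11, 8 and 5 with CL6G36, CL6G45 and CL6G52 (6 or 11, 4 or 11 and 2 or 3 with split controls), and 1, 2 and 0 calls went in opposite directions. Its r was 0.396, 0.409 and 0.396, against simulated values of 0.50, 0.50 and 0.498, and its covariance 0.0527, 0.0540 and 0.0456, against 0.0364, 0.0362 and 0.0363. The simulated r comes from shared arrays in unchanged groups and is no baseline for changed ones. With split controls the r of CL6G26 was 0.0316 or 0.124, 0.0322 or 0.139 and 0.0636 or 0.0368. That of CL6G36 with CL6G45 was then 0.324 or 0.338. For CL6G52 it was 0.234 or 0.117 with CL6G36 and 0.281 or 0.145 with CL6G45. Differences between sublines at the level of lists were not tested.

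Called the same way in all 4 sublines were 3 genes, all lower than in P19CL6, and 42 passed by adjusted p alone. The count was 6 without P19CL6 replicate 2 or CL6G26 replicate 1, 5 without P19CL6 replicate 1, and 2 without P19CL6 replicate 3 or 4 or CL6G52 replicate 5. Over the other alternatives it ran from 2 to 7. Lgals3 was at least 8.48-fold lower in CL6G26, CL6G36 and CL6G45 and fell by 2.57 on the log2 scale in CL6G52 (adjusted p = 0.0379), where 4 of 5 arrays lay above the floor and the call was lost under 11 of 22 alternatives. Its mean was 7.70 in P19CL6. Ifitm1 was at 8.05 in P19CL6 and at 6.55, 4.48, 5.21 and 5.70 in CL6G26, CL6G36, CL6G45 and CL6G52. Cited2 was at 7.11 in P19CL6 and changed by -1.71, -1.27, -1.84 and -1.36 in the same order.

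**Figure D4:**
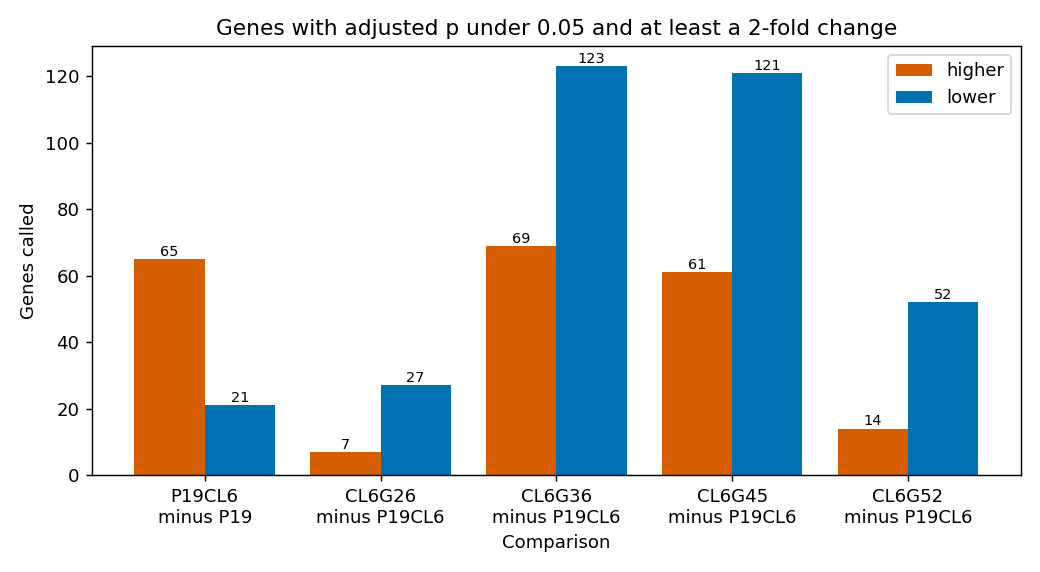
Number of genes called higher and lower in each of the 5 comparisons, as bars that start at 0. CL6G36 and CL6G45 have 192 and 182 called genes, against 34 in CL6G26 and 66 in CL6G52.

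Of 140 list tests 41 passed the threshold and 24 held with an estimated correlation. With the arrays relabelled over all strains, a median of 9 tests passed, and at most 34. A single list call at the preset correlation can thus arise without the strain grouping. In the data as labelled, 14 lists passed in at least 1 comparison. The other tested lists passed in none. List tests and medians used the members read on MOE430A, which for the lists above were 28 of 29 for cell cycle, 16 of 18 for Wnt, 16 of 17 for cholesterol, 15 of 16 each for streak, BMP and FGF, 12 of 13 for interferon and 8 of 10 for contractile genes. The others of the lists above had all their tested members there. For the lists that passed in none, members are counted on MOE430A. Their lowest adjusted p values were 0.178 for shared pluripotency genes (16 members, medians from -0.09 to 0.08), 0.176 for naive pluripotency genes (9 members, -0.43 to 0.00), 0.176 for cardiac transcription factors (11 members, -0.13 to 0.03) and 0.231 for neural genes (14 members, -0.18 to -0.00). Markers of other cell types gave 0.0542 for trophoblast genes (8 members, -0.29 to 0.09), 0.493 for blood and endothelial genes (6 members, -0.15 to 0.07) and 0.176 for fibroblast genes (7 members, -0.12 to 0.13). Notch genes gave 0.123 (14 members, -0.13 to 0.09), retinoid genes 0.320 (10 members, -0.21 to 0.05), imprinted genes 0.0656 (19 members, -0.21 to 0.06) and oxidative phosphorylation genes 0.147 (24 members, -0.04 to 0.06). Extracellular matrix and adhesion genes gave 0.176 (23 members, -0.15 to 0.08), ribosomal protein genes 0.258 (20 members, -0.03 to 0.04), and DNA and histone methylation enzymes 0.231 (18 members, -0.06 to 0.03).

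The median, mean and test of a list had the same sign in every list call, and differed in 26 of the 99 tests that missed the threshold, over 17 lists, with a lowest adjusted p of 0.208. Germ cell, Y chromosome and X inactivation lists had 3, 3 and 2 tested members and were not tested as lists. Of these members Asz1, of the germ cell list, fell in CL6G45 by 0.68 on the log2 scale (limma, adjusted p = 0.0249), while Dppa3 and Rnf17 passed in no comparison. Kdm5d, a Y-linked demethylase, rose by 0.80 in P19CL6 against P19 (adjusted p = 0.0125), Eif2s3y, a Y-linked translation factor, rose by 0.56 in CL6G45 (adjusted p = 0.0136), and Uty passed in none. The call of Kdm5d was lost under 6 of 22 alternatives, that of Asz1 under 4 and that of Eif2s3y under 2. Xist and Jpx, RNAs of X inactivation, passed in none.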

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

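The tests of explanations and the counts over other splits were chosen after the results they bear on were seen; the F test among sublines was planned.

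P19 replicates 4 and 5 carried P19CL6-like levels of Cited1, Trh, Meg3, Dppa4 and Bhlhe40. On a line from P19 replicates 1 to 3 (position 0) to P19CL6 (position 1), with each array left out of its own mean, they stood at 0.914 and 0.912 on MOE430A, P19 replicates 1 to 3 at 0.182 to 0.251 and P19CL6 at 0.868 to 0.920; on MOE430B, where the groups lie closer, they stood at 0.743 and 0.763, against 0.504 to 0.546 and 0.697 to 0.737. A swap of labels with P19CL6 is argued against by the lowest P19CL6 position, 0.868, since no P19CL6 array lay with P19 replicates 1 to 3, and a mixture with a large share of such RNA by the lower of the 2 positions, 0.912. P19CL6 RNA under a P19 label stays open: both arrays correlated best with the P19CL6 mean on both array types (lower r across genes 0.362 on MOE430A and 0.105 on MOE430B), yet their Gapdh ratios on MOE430A, 0.954 and 0.923, lay above the P19CL6 range of 0.835 to 0.887, as did those of P19 replicates 1 to 3, while on MOE430B they were 0.882 and 0.841, against a P19CL6 range of 0.829 to 0.878 and 0.815 in P19 replicate 3. The same positions argue against a P19 culture with a large share of cells like those of replicates 1 to 3. P19 cultures that differ from each other in state may also give such arrays, and no biological explanation was tested.

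Between CL6G52 replicates 2 to 5 and CL6G45, the position of CL6G52 replicate 1 on MOE430A was 0.812, against 0.187 to 0.244 in replicates 2 to 5. On MOE430B, where the groups lie closer, it was 0.637, against 0.447 to 0.538 in replicates 2 to 5 and 0.555 to 0.640 in CL6G45. A swap with CL6G45 is argued against by the lowest CL6G45 position, 0.829, and a mixture with a large share of CL6G52 RNA by the position of the array itself, 0.812. CL6G45 RNA under a CL6G52 label may account for it, since the array correlated best with the CL6G45 mean on MOE430A (r = 0.404) and less closely on MOE430B (r = 0.175). Trh read 5.95 in it, 1.05 to 2.08 in replicates 2 to 5 and 5.90 to 6.23 in CL6G45. Ddit3, at 8.01, also lay inside the CL6G45 range of 7.88 to 8.39. Other genes lay outside the CL6G45 range. Hspa5 read 12.26 against 12.05 to 12.14, and Bhlhe40 read 7.85 against 7.17 to 7.68. Lgals3, under the floor in all of these arrays, read 4.28 against 0.94 to 3.61. The match to CL6G45 is thus not complete, and no biological explanation was tested.

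Unfolded protein response genes were higher in CL6G36 and CL6G45 than in P19CL6. Scaling between arrays is argued against by the medians of the list, the lowest of which was 0.663 over 3 scalings and both sublines. The list also passed under each scaling. That adds little, since camera sets a list against other genes and a shift of a whole array largely cancels there. RNA quality cannot be told apart from the subline, since 0 of their 10 samples had a Gapdh ratio inside the range of P19CL6 on both array types. On MOE430A alone the 4 arrays inside it had list means of 9.10 to 9.19, the lowest of them 0.379 above the highest of P19CL6, and the 6 outside it 9.21 to 9.39, but on MOE430B the same 4 samples had ratios of 0.801 to 0.825, below the P19CL6 range of 0.829 to 0.878. CL6G52 replicates 3 and 5 had ratios below the P19CL6 range on both array types. They were 0.781 and 0.830 on MOE430A and 0.786 and 0.767 on MOE430B. The list means of CL6G52 ran from 8.11 to 9.14, with replicate 1 highest and apart by 0.806 of that range. Its other replicates thus lay below the highest of P19CL6, 8.72. This argues against a low ratio alone raising the list, for that subline. A difference between the sublines and P19CL6 in protein folding load may also account for the higher list in CL6G36 and CL6G45 and was not tested.

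Single arrays stood apart from the other 4 of their strain by a gap, as a share of the strain's range, above the 95% critical value of 0.71. By gene these were Snx7 in CL6G36 replicate 5 (0.812), Ifitm1 in CL6G45 replicate 1 (0.717) and CL6G52 replicate 1 (0.869), Tmem98 in P19CL6 replicate 5 (0.735), Mfsd6 in CL6G45 replicate 2 (0.813) and Gata4 in CL6G45 replicate 4 (0.72). Frmd4a (0.771), Crabp2 (0.863) and 1 further gene (0.791) stood apart in CL6G52 replicate 1. By list mean, CL6G52 replicate 1 stood apart for glycolysis (0.848), cholesterol synthesis (0.908), cell cycle (0.719), p53 target (0.884), unfolded protein response (0.806) and heat shock genes (0.854). Cardiac contractile genes stood apart in CL6G36 replicate 2 (0.91), Wnt ligands and targets in CL6G52 replicate 3 (0.774) and interferon and MHC genes in CL6G26 replicate 2 (0.831). Chance gives about 1 in 20 groups: 8.35 of 167 gene groups and 4.2 of 84 list groups, against 9 and 9 found, of which 4 and 6 came from CL6G52 replicate 1.

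The difference from P19CL6 differed among the 4 sublines for 398 genes. Probe sets without a single gene name, 4564 of those tested, were used in no comparison of genes, and 15 of them passed the same thresholds for P19CL6 against P19, 5 for CL6G26, 21 for CL6G36, 29 for CL6G45 and 6 for CL6G52.

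In 100 splits of the arrays, the real one included, 6 gave as many calls as the 86 of P19CL6 against P19. The highest other split gave 97 and put P19 replicate 5 with P19CL6 replicates 1, 2, 4 and 5, so that P19 replicates 1 to 3 again stood on the other side. Splits that keep those arrays together carry their difference from the others, so their counts do not measure chance. The splits thus neither exclude chance for the 86 genes nor show it. Each of the other counts was reached by 1 of 100 splits or relabellings, the real one, the lowest share that 100 could give. CL6G26 had 34 genes against a highest other of 3, CL6G36 192 against 38, CL6G45 182 against 29 and CL6G52 66 against 22. The sublines had 398 genes against 61, and 41 lists stood against 34, with a median of 9 over the other relabellings. The 3 genes in all 4 sublines stood against 0. The relabellings for that count mixed P19CL6 with the sublines, which takes away the differences between strains. They cannot show what the shared P19CL6 arrays add to it, so sharing by chance is not excluded there.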

How the results depend on the processing

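The fits without P19 replicates 4 and 5, and without these and CL6G52 replicate 1, were chosen after the data were seen; the other alternatives were planned. No gene given above with a fold change past the threshold, other than from the test among sublines, changed sign and no list call changed the direction of its test under any alternative run, but the medians of primed epiblast genes in CL6G45 and CL6G52 crossed 0.

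The count for P19CL6 against P19 moved from 86 to 47 with the deposited scaling and to 0 with the 2 strains alone in limma (2133 genes at an unadjusted p under 0.05), which estimates the wide spread of P19 from these arrays alone. It was 390 without P19 replicates 4 and 5 and 394 without these and CL6G52 replicate 1; leaving out the arrays that lie nearest to P19CL6 raises it by construction. With 1 array left out it ran from 0 (without P19 replicate 1, 2 or 3) to 198 (without P19 replicate 4), and was 192 without P19 replicate 5. CL6G26 moved from 34 to 22 with the deposited scaling. With signals raised to the floor CL6G45 moved from 182 to 112 and the sublines from 398 to 236, since genes under the floor in a group then count with smaller changes. The 3 genes changed in all 4 sublines became 5 with median centring, 6 with signals raised to the floor and 7 with the 2 strains alone, and the cause was not tested. The 41 list calls became 24 with an estimated correlation, which allows for members that vary together, and 57 with fry, which asks another question.

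With 1 array left out the counts ran from 29 to 37 in CL6G26, 176 to 217 in CL6G36, 166 to 199 in CL6G45, 45 to 74 in CL6G52, 366 to 508 among the sublines, 2 to 6 in all 4 sublines and 39 to 45 for lists. The 6 came without P19CL6 replicate 2 or CL6G26 replicate 1, and 5 without P19CL6 replicate 1; the 2 came without P19CL6 replicate 3 or 4 or CL6G52 replicate 5.

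With the replicate number as a block the counts were 85, 34, 194, 181 and 64 for P19CL6 against P19, CL6G26, CL6G36, CL6G45 and CL6G52, with 399 among the sublines, 3 in all 4 and 41 lists, all within 1.5 times. The numbers do not pair the samples: over 75 same-numbered pairs r ran from -0.154 to 0.112 on MOE430A and from -0.044 to 0.0579 on MOE430B, and 10% and 20% of arrays correlated best with their own number.

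Over the alternatives other than those with 1 array left out, named genes stayed on their side of the threshold 2948 times, lost the call 183 times and gained it 17 times, 3 values with no call moved past their spread and changed sign, and list calls held 532 times and were lost 42 times, with fry counted among the alternatives. With 1 array left out, named genes held 2393 times, lost the call 228 times and gained it 9 times, and list calls held 1211 times and were lost 19 times. Signal over background limits genes near the floor. Their changes are given as bounds where all arrays of a group lay under it, and otherwise as fitted or with signals raised to it.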

Other observations

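The genes of the opening paragraph and the tests of relations between lists were chosen after their values were seen.

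Against P19CL6, 34 genes were called the same way in CL6G36, CL6G45 and CL6G52, of which 4 were higher and 30 lower. In CL6G26, 31 of them were not called, which does not show that they were unchanged there. As fitted, all of these but Alox15, Foxa2, Lhx1 and Slc35d3 moved the same way in CL6G26. Nkx1-2, Fst, Egr1 and Dact1 changed there by -0.98, -0.78, -0.96 and -0.45 (limma, highest adjusted p = 0.041, for Egr1), short of 2-fold. Sp5, Sall3 and Irx3 changed there by -1.39, -1.06 and -1.02 but missed the adjusted p threshold. The comparisons of CL6G36, CL6G45 and CL6G52, and that of CL6G26, share the P19CL6 arrays. Unchanged groups simulated against these arrays shared at most 0 calls, but such groups have few calls to share. With P19CL6 replicates 1 and 2, 3 and 4, and 5 given to 1 comparison each, 9 to 17 were shared. Without CL6G52 replicate 1, which lies with CL6G45, 31 were shared. Calcr, the calcitonin receptor, was higher by 1.86, 1.82 and 1.21 on the log2 scale in CL6G36, CL6G45 and CL6G52. Slc35d3, a transporter-like protein, was higher by 1.93, 1.90 and 1.54 with signals raised to the floor, above which it lay on 2 of 5 arrays of P19CL6. Among the lower genes, Aplnr, the apelin receptor of early mesoderm, was at least 2.34-fold lower in each. Sgk1, a kinase induced by serum and glucocorticoids, changed by -1.57, -1.25 and -1.18, and Dact1, an antagonist of Wnt signalling, by -1.37, -1.14 and -1.30. With signals raised to the floor, above which they lay on 1 to 4 of 5 arrays of each of these sublines, Cyp26a1, which degrades retinoic acid, changed by -1.48, -1.06 and -1.40, Irgm1, an interferon-induced GTPase, by -1.37, -1.40 and -1.11, and Rtl8c, a gene derived from a retrotransposon, by -1.80, -1.97 and -1.99. The call of Cyp26a1 in CL6G45 was lost under 3 of 22 alternatives, that of Irgm1 in CL6G52 under 2 and that of Aplnr in CL6G52 under 1.

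Over all 30 arrays with strain means taken off, 3 relations between list means were tested with 100000 permutations. A hypothesis that unfolded protein response genes are high where primitive streak genes are low was not borne out (r = -0.188, rho = -0.176, permutation p = 0.482 for r, adjusted p = 0.723); r was -0.156 without the 2 arrays farthest on the x axis and -0.449 without the 3 arrays that lie with another strain (adjusted p = 0.131). A hypothesis that unfolded protein response and glycolysis genes are high together gave r = 0.683 and rho = 0.625 (permutation p = 0.00201 and 0.00139, adjusted p = 0.00603 for r). Without the 2 farthest arrays, CL6G52 replicate 1 and P19CL6 replicate 2, r was 0.328, and without the 3 arrays r was 0.348 (adjusted p = 0.131), so the relation rests on those arrays and may reflect the array that lies with CL6G45. Glycolysis against primitive streak genes gave r = 0.0527, rho = 0.0185 and adjusted p = 0.821.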
